A study of Populus tremula x Populus tremuloides with 6 samples.

How the data were processed

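Leaf RNA from 6 hybrid poplars (Populus tremula x Populus tremuloides) was sequenced, 3 wild-type plants and 3 transgenic plants that overexpress MYB117. Per the labels' protocols, excised leaves of a clone of this hybrid were transformed, with the MYB117 vector carried by Agrobacterium tumefaciens. Per the labels' protocols, the plants spent 1 month in a mist chamber and 2 months in a greenhouse, and leaves 7 to 10, counted by the leaf plastochron index from the top of the shoot, were taken. Messenger RNA was enriched, fragmented by heat and made into cDNA libraries, and fragments of a chosen size were kept, per the same protocols. Whether the 3 transgenic plants came from different transformation events is not given in the sources used here. The p-values below measure the spread between these plants, except those of Fisher's exact test, camera and shuffled calls, which compare sets of loci.

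The deposited values are raw read counts, whole numbers per locus and library with no normalization. HISAT2 2.1.0, Cufflinks and HTSeq 0.6.1 are named in the submitters' processing notes. The genome build, the annotation and the counting options, strand among them, are not given in the sources used here. Each file lists 37662 loci under numbers of the kind that Cufflinks assigns. Of these, 34267 carry a gene identifier that starts with Potra (33476 distinct identifiers, 775 of them on more than 1 locus), 425 carry the name of a microRNA hairpin, 2946 carry NA and are called unnamed loci here, and the others carry other labels. The last 5 rows count reads that were given to no locus. They were left out of library sizes and tests, and they held from 27.0% to 29.6% of the reads of a library. Reads that overlapped more than 1 locus were among them, at 10.1% to 12.5%, so overlapping loci are undercounted, and values of near-identical gene copies and of genes that overlap on opposite strands are uncertain.

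The files pair no identifier with a gene name or a product name. Before the data were examined, 27 gene lists were fixed for this comparison, for flavonoid and anthocyanin synthesis, lignin, photosynthesis, stress, cell division and markers of xylem, phloem and epidermis. They held 64 gene identifiers of another poplar annotation and search words for product names. As 0 of the 64 identifiers occurred in the files, these lists, the level of MYB117 itself and the planned ratio of flavonoid B-ring hydroxylases were not analysed here. No value below therefore checks the labels of the transgenic plants. The microRNA hairpin names were used in their place. They were grouped into 10 lists by their known targets or, for the list of Populus families, by lineage. This was done after the names had been read and before their counts were looked at. Markers of other cell types were not analysed here.

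Counts of the 6 libraries were tested with the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3), two-sided, MYB117 overexpression against wild type, with TMM scaling, the expression filter of edgeR (a minimum count of 10 and a total of 15), no covariate and Benjamini-Hochberg adjustment over the 26854 loci that passed the filter. A locus was called changed at an adjusted p below 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels of single loci and families are CPM, the counts-per-million of the reads in loci, as mean ± SD of 3 libraries. They were computed from the deposited counts without TMM scaling. TMM-scaled CPM were used for counts of loci by mean level, class medians, level matching, correlations, principal components and the rule for named loci. Where a group had 0 counts in all libraries, the fold is a lower bound, computed against 3 counts per library. Intervals of odds ratios treat loci as independent units. Fold bounds and the limits for counts of 0 cover counting error only. Lists with at least 3 tested members were tested with camera of limma 3.58.1, once with a preset correlation of 0.01 between loci and once with an estimated one, and with fry. Classes of loci were compared by Fisher's exact test, and read shares of the libraries by an exact two-sided permutation test, whose smallest p with 3 against 3 is 0.1. The latter were adjusted over 13 library measures. These include the read shares of loci called higher and lower, whose p follows from the choice of those loci on the same libraries. Including these shares makes the adjusted p of the other measures with a p of 0.1 smaller than it would be without them.

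The rule for named loci, fixed before the data were examined, took the 8 largest rises and the 8 largest falls among changed loci with a mean of at least 1 CPM and no overlap between the groups. As the identifiers stand without gene names, 2 of each are printed and the others are described by their levels. Hairpin loci that passed the test were named in addition, and the other hairpins in the text were chosen after their values were seen. On simulated counts with the levels and depths of these libraries and the trend of their spread with level (26616 loci in the step), the test recovered 9 of 100 loci changed 2-fold and 69 of 100 changed 4-fold, with 4 false calls. No other loci were changed there, whereas 17.1% of tested loci were called in the data, and the adjustment is stricter when fewer loci change. These recoveries therefore do not measure the sensitivity of the real comparison. The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma voom, 2 other count filters, the replicate number as a block, and each library left out in turn. Alternatives added after seeing the data are named with their results. No 2 libraries were duplicates: the closest pair of a group differed by 37.2 times the sampling noise (chi-square per degree of freedom).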

Results

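The transcriptomes of leaves from 3 wild-type and 3 MYB117-overexpressing hybrid poplars were compared by RNA sequencing of greenhouse-grown plants. MYB117 belongs to the MYB family of plant transcription factors, in which many regulators of anthocyanin and other phenylpropanoid synthesis are found. The comparison asks which leaf transcripts differ when this factor is overexpressed. Reads in loci numbered 28960403, 37631885 and 38013856 in wild-type replicates 1, 2 and 3, and 42410466, 49442174 and 35164729 in MYB117 replicates 1, 2 and 3. Between 29924 and 31155 loci had at least 1 read in a library. Libraries of the same group correlated at 0.915 to 0.980 across loci (Pearson, log2 CPM), and libraries of different groups at 0.844 to 0.901. The first principal component held 61.2% of the variance and separated the groups. The second, with 22.2%, set replicate 1 of each group apart from the other libraries.

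Leaves of the MYB117 plants differed from wild-type leaves at 4599 of 26854 tested loci, of which 2669 were higher and 1930 lower. Large changes were mostly rises: 402 loci were at least 16-fold higher and 28 at least 16-fold lower, and at 64-fold the numbers were 128 and 2. Of the loci at least 2-fold changed, 2139 were higher and 1362 lower. Loci called higher held 4.47% ± 0.67 of the reads in wild-type libraries and 18.2% ± 0.14 in MYB117 libraries (n = 3 each). Loci called lower held 14.3% ± 0.41 and 6.55% ± 0.82. These shares describe loci chosen on the same libraries and are not a separate test. They moved with the calls: with the loci called without wild-type replicate 2, or without MYB117 replicate 1, 2 or 3, the share of MYB117 reads in higher loci was 11.8%, 13.5%, 10.9% or 11.4%, and the share of wild-type reads in lower loci 6.23%, 6.49%, 1.26% or 2.44%. With the loci called by DESeq2 they were 24.9% and 31.2%, and with those called without the libraries numbered 1 they were 21.04% and 33.3%. Calls are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 10909 loci (40.6% of those tested) had no overlap between the groups, against 10% by chance.

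**Figure D1:**
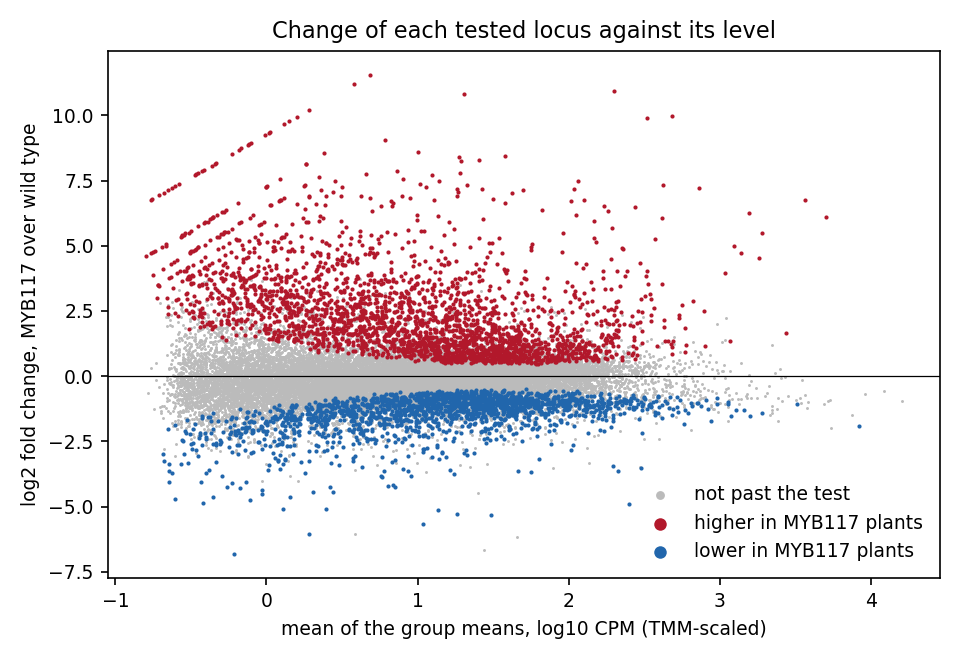
Each point is 1 of the 26854 tested loci, with its mean level (log10 CPM, TMM-scaled) on the x axis and its log2 fold change, MYB117 over wild type, on the y axis. Red points (2669) were higher and blue points (1930) lower at an adjusted p below 0.05, and grey points did not pass the test; the red points reach much larger changes than the blue ones, and the slanted rows at the left edge are loci with 0 to a few reads in wild type.

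Many of the rises began from almost no transcript. Of the 2669 loci called higher, 288 had a wild-type mean below 0.1 CPM and 881 below 1 CPM, whereas 35 and 288 of the 1930 loci called lower had such means in the MYB117 plants. At 43 loci no wild-type library had a read while each MYB117 library had at least 10. The opposite was seen at 0 loci. Some of the transcripts that rose became abundant: 43 loci that rose at least 16-fold exceeded 100 CPM in the MYB117 plants and 8 exceeded 1000 CPM, against 1 and 0 loci with falls of that size and those levels in wild type. The 8 loci together held 0.066% ± 0.017 of wild-type reads and 3.51% ± 0.14 of MYB117 reads (n = 3 each).

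**Figure D2:**
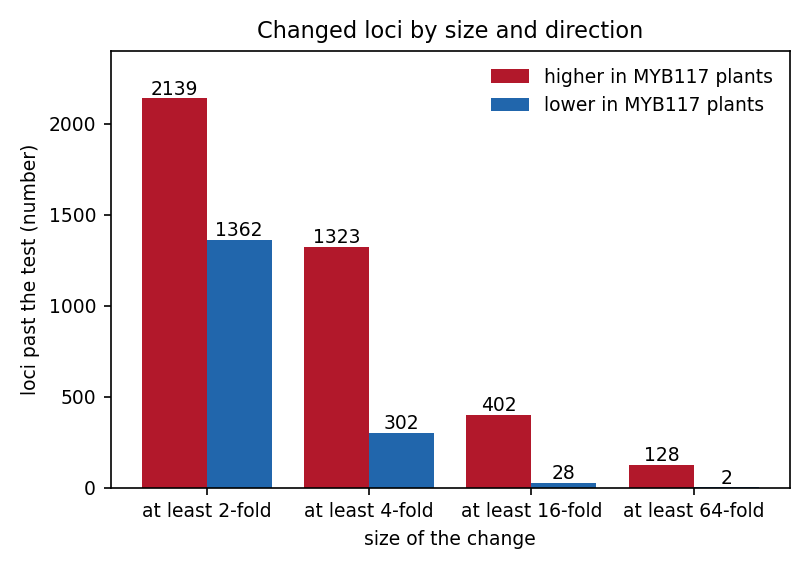
Bars give the number of loci past the test (y axis) at or above each size of change (x axis), red for loci higher and blue for loci lower in the MYB117 plants. The excess of rises grows with the size of the change, from 2139 against 1362 loci at 2-fold to 128 against 2 at 64-fold.

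The locus ranked first by its fitted rise, Potra002756g19911, had 0 reads in all 3 wild-type libraries and 9.87 ± 3.04 CPM in the MYB117 plants, at least 113-fold higher (adjusted p = 0.0025, edgeR). Where wild type has 0 reads, the fitted value depends on a small count that the method adds. The log2 fold change of this locus, 11.56, was 10.80 with DESeq2 and 9.26 with limma voom, where other loci of the 8 largest rises ranked above it. The next, Potra003179g20912, was likewise at 0 in wild type and reached 7.85 ± 1.51 CPM, at least 89.8-fold higher (adjusted p = 0.0012, edgeR). The other 6 of the 8 largest rises had means of 3.33 to 1002 CPM in the MYB117 plants and at most 0.922 CPM in wild type. The most abundant of them went from 0.922 ± 0.250 to 1002 ± 225 CPM, a rise of 1086-fold (log2 fold change 9.98, SE 0.37, adjusted p = 0.00013, edgeR). Another went from 0.660 ± 0.109 to 677 ± 30.1 CPM (1027-fold). The largest measured folds of the 8 were 2377-fold, from 0.0176 ± 0.0153 to 41.9 ± 7.36 CPM, and 2115-fold, from 0.196 ± 0.065 to 415 ± 28.8 CPM. The former had at most 1 read in a wild-type library. Each of the 8 passed the test in the same direction under every alternative that was run.

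Falls were smaller. Potra002398g18252 fell from 3.86 ± 2.95 CPM to 0.054 ± 0.077 CPM (log2 fold change -6.05, SE 1.12, adjusted p = 0.016, edgeR), and Potra002011g15769 from 22.3 ± 33.7 to 0.418 ± 0.278 CPM (log2 fold change -5.68, SE 1.45, adjusted p = 0.041, edgeR). The former lost its call without MYB117 replicate 2 or 3, at log2 fold changes of -5.59 and -5.55 (adjusted p = 0.071 and 0.059, edgeR), and its log2 fold change was -8.07 without MYB117 replicate 1 (adjusted p = 0.029, edgeR). The latter rests largely on wild-type replicate 2, without which its log2 fold change was -2.93 (adjusted p = 0.051, edgeR). It also lost its call without any 1 of the MYB117 libraries (adjusted p = 0.094 to 0.14, edgeR) and with limma voom (adjusted p = 0.17). DESeq2 gave it no adjusted p, and Potra002398g18252 did not pass the minimum of 1 CPM in 3 libraries. The most abundant of the 8 largest falls went from 468 ± 81.5 to 16.3 ± 5.26 CPM, 28.7-fold lower (log2 fold change -4.91, SE 0.35, adjusted p = 0.00076, edgeR). The means of all 8 in the MYB117 plants lay between 0.054 and 16.3 CPM.

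The numbers of changed loci depended on which libraries were used. Leaving out wild-type replicate 2 gave 1573 higher and 669 lower loci, and leaving out MYB117 replicate 1, 2 or 3 gave 1598, 1236 or 1265 higher and 719, 316 or 443 lower loci. Leaving out wild-type replicate 3 gave 2363 higher and 1513 lower loci. The numbers were larger without wild-type replicate 1, at 2839 higher and 2273 lower, and without both libraries numbered 1, at 2902 and 2685. Loci at least 2-fold changed numbered 1216 to 2262 higher and 313 to 1543 lower with 1 library left out, the lowest of both without MYB117 replicate 2. The number of falls of at least 16-fold, 28, was 18 without MYB117 replicate 3, 73 without the libraries numbered 1, 50 with DESeq2 and 15 with a minimum of 1 CPM in 3 libraries. DESeq2 called 3959 higher and 3416 lower. In the refits, 0 of the 4599 loci had a fold change of the opposite sign, where 4206 of them were tested with the minimum of 1 CPM, 4527 in counts thinned to the smallest library and all 4599 in the other alternatives. These loci were chosen on libraries that the refits use again, so the kept signs are not a separate test.

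Unnamed loci, transcribed regions to which the files give no identifier, changed mostly upwards. Of 2781 tested, 439 were higher and 94 lower, so that 82.4% of the changed ones rose. Among the 24042 tested loci with a Potra identifier, 2229 were higher and 1835 lower, or 54.8% of the changed ones. The odds of a rise among changed loci were 3.84 times as high for unnamed loci (95% interval 3.04 to 4.90, Fisher's exact test, p = 8.5e-37), although loci are not independent replicates, and 8.08 times as high without MYB117 replicate 3. Unnamed loci held 2.77% ± 0.14 of the reads in loci of wild-type libraries and 3.32% ± 0.28 in MYB117 libraries, a difference with an exact permutation p of 0.1, the smallest that 3 against 3 can give (0.16 after adjustment over 13 library measures). The median level of a tested unnamed locus was 2.17 CPM, against 12.1 CPM for loci with an identifier.

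Named loci in the files are microRNA hairpins, and 6.67% of the 30 tested changed, against 17.1% of all tested loci, a difference that was not tested. MicroRNAs are cut from long hairpin transcripts, and a library of long messenger RNA reads the precursor or an overlapping transcript, not the mature microRNA. Of 425 hairpin loci in 102 families, 304 had 0 reads in all 6 libraries and 30 passed the filter. One of the 30 rose and 1 fell when adjusted over all loci, and 0 passed when adjusted over the list alone (edgeR, adjusted p = 0.055 for both), while 4 had an unadjusted p below 0.05. Over all 26854 tested loci, 8922 had such an unadjusted p. DESeq2 called 6 hairpin loci over all loci and limma voom 2. With 1 library left out the number was 0 to 4, the highest without wild-type replicate 1. The hairpin locus ptc-MIR169m fell from 3.65 ± 0.12 to 0.635 ± 0.551 CPM (log2 fold change -2.66, SE 0.61, adjusted p = 0.029, edgeR). The MIR169 family is known for targeting transcripts of NF-YA transcription factor subunits. The locus ptc-MIR530a rose from 1.495 ± 0.476 to 5.27 ± 2.097 CPM (log2 fold change 1.75, SE 0.40, adjusted p = 0.030, edgeR). Both calls were lost when some of the single libraries were left out. The call of ptc-MIR169m was lost without wild-type replicate 2 or 3 or without MYB117 replicate 1 or 2 (log2 fold change -2.24 to -2.73, adjusted p = 0.051 to 0.11, edgeR), and that of ptc-MIR530a without any 1 library except wild-type replicate 3 (log2 fold change 1.31 to 1.97, adjusted p = 0.055 to 0.099, edgeR). Without MYB117 replicate 3 the log2 fold change of ptc-MIR169m was -3.55 (adjusted p = 0.021, edgeR).

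Summed over its 27 loci, the MIR169 family fell from 4.93 ± 0.50 to 1.68 ± 0.50 CPM (log2 fold change -1.64, SE 0.27, adjusted p = 0.015 over 25 tested families, edgeR). Without ptc-MIR169m the log2 fold change of the family was -0.34 (adjusted p = 0.58). It was the 1 family past the test, the fit by family was chosen after seeing the data, and the call was lost without wild-type replicate 2 or 3 or MYB117 replicate 1 or 2 (log2 fold change -1.47 to -1.66, adjusted p = 0.056 to 0.091, edgeR). Among hairpins that did not pass the test, ptc-MIR472a, of a family that targets disease resistance transcripts, was at 7.19 ± 1.13 and 4.41 ± 0.88 CPM (adjusted p = 0.066, edgeR), ptc-MIR166c, of a family that targets leaf polarity regulators, at 24.4 ± 19.04 and 11.6 ± 3.63 CPM (adjusted p = 0.20, edgeR), and egu-MIR172d, the most abundant, at 419.6 ± 91.0 and 419.1 ± 28.4 CPM (adjusted p = 0.79, edgeR).

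**Figure D3:**
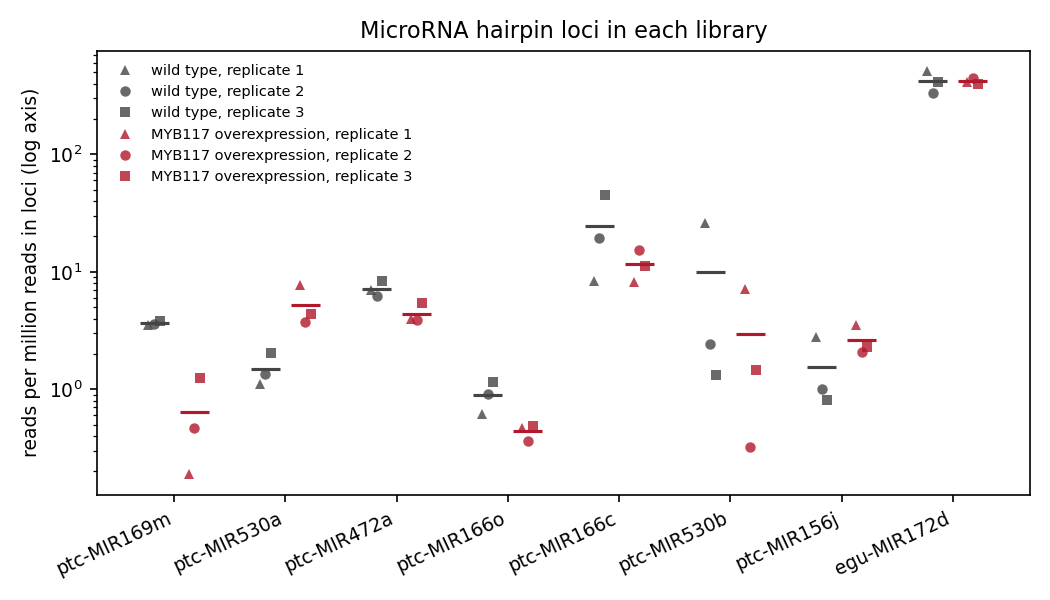
Points are the level of each hairpin locus in each library (CPM, log y axis), grey for wild type and red for MYB117 overexpression, with a symbol for each replicate number and a line at the group mean. The 3 wild-type libraries lie above the MYB117 libraries at ptc-MIR169m and below them at ptc-MIR530a, while at ptc-MIR530b replicate 1 is the highest library of each group.

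No hairpin list passed the test of a shared direction. Of the leaf development list, 6 hairpins were tested, with 0 past the test and a median log2 fold change of -1.12 (camera adjusted p = 0.28, and adjusted p = 0.92 with an estimated correlation). The median was -0.39 without wild-type replicate 3, -0.22 with no count filter and -0.67 with the minimum of 1 CPM. The filter and the libraries used decide which hairpins are tested, so these medians need not cover the same 6 hairpins. Of the list of families that target SPL and AP2 transcripts, 5 were tested, with 0 past the test and a median of -0.12 (camera adjusted p = 0.89, and adjusted p = 0.92 with an estimated correlation). The 30 tested hairpins together had a median of -0.21 (camera adjusted p = 0.61, and adjusted p = 0.92 with an estimated correlation), and fry gave p = 0.31 for a shared direction and p = 0.0021 for changes in either direction. The last test asks only whether any of the 30 changed, not whether hairpins changed more than other loci. Of all 26854 tested loci, 8922 had an unadjusted p below 0.05 (edgeR), so a small value is not particular to hairpins. The MIR828 family, which targets MYB transcripts that control anthocyanin synthesis, had 1 read at ptc-MIR828b in 1 wild-type library and 0 elsewhere over its 2 loci, so a change was not detectable at this depth. Counts of 0 allow up to 0.061 to 0.104 CPM in these libraries. Each of the other 7 lists (copper, phosphate and sulfate, resistance genes, auxin receptor, NF-Y, small RNA machinery and Populus families) had at most 2 tested hairpins and was not tested as a list.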

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

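Some kinds of reads outside the tested loci differed between the groups, and all tests of this pattern were chosen after the result was seen. Reads that did not align made up 7.62% ± 0.42 of all reads in the MYB117 libraries and 6.52% ± 0.17 in wild type. Alignments of low quality made up 5.99% ± 0.15 and 5.78% ± 0.04, and reads with several alignments 2.34% ± 0.13 and 2.12% ± 0.09. In each of the 3 measures every MYB117 library lay above every wild-type library, which 3 against 3 turns into an exact permutation p of 0.1, the smallest possible (0.16 after adjustment over 13 library measures). Reads outside any locus went the other way, at 1.37% ± 0.09 and 1.80% ± 0.41 (exact permutation p = 0.1). All reads outside the loci overlapped between the groups, at 28.3% ± 1.29 and 27.5% ± 0.48 (exact permutation p = 0.4), as did reads on more than 1 locus, at 10.97% ± 1.37 and 11.3% ± 0.46 (exact permutation p = 0.8).

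Sequencing depth may account for part of the difference in unaligned reads, since the MYB117 libraries were deeper on average. With a linear term for the number of reads in all over the 6 libraries, 0.732 of the 1.10 percentage points between the groups were left. MYB117 replicate 3 had fewer reads in all than wild-type replicates 2 and 3 and a higher share of unaligned reads, 7.27% against 6.52% and 6.69%, which speaks against depth as the whole source but rests on 1 library. An exact test of 3 against 3 cannot give a p below 0.1, and the difference left in the linear fit was not itself tested, so depth stays open. Transcripts of the introduced gene construct that do not align to the reference may be another source. The excess was 10995 reads-per-million of all reads, below the 16321 that the most abundant locus reached in any library on the same base, so a single very abundant transcript could hold it, and counts without sequences leave this open. Differences in library quality were not tested.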

How the results depend on the processing

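Alternatives chosen after seeing the data were the fit without the libraries numbered 1, the thinned counts, the hairpin families, the family without ptc-MIR169m, the matching on level and the 16-fold limit. RLE and upper-quartile scaling, limma voom and no count filter kept every count of loci within 1.5 times and gave shares of rises among the calls of 56.2% to 60.1%, against 58.0%. With DESeq2, 3416 loci were lower, 2176 at least 2-fold lower and 50 at least 16-fold lower, and 4598 of the 4599 calls were shared. With a minimum of 1 CPM in 3 libraries, 15 loci were at least 16-fold lower. Leaving out 1 library gave 1236 to 2839 higher and 316 to 2273 lower loci, 1216 to 2262 at least 2-fold higher, 313 to 1543 at least 2-fold lower, 358 to 457 at least 16-fold higher and 18 to 41 at least 16-fold lower. The fewest calls came without MYB117 replicate 2 (1552, of which 1540 were shared) and the most without wild-type replicate 1 (5112, of which 3969 were shared), while the 16-fold counts were lowest without MYB117 replicate 3. Without the libraries numbered 1 there were 2902 higher and 2685 lower loci, 73 of them at least 16-fold lower; the cause was not tested. The median of the SPL and AP2 hairpin list, -0.12 with all libraries, was -0.26 to 0.15 with 1 library left out: 0.15 without wild-type replicate 1 and 0.07 without MYB117 replicate 2. It was 0.11 without the libraries numbered 1, and did not pass the test in any of these fits. The median of the leaf development list, -1.12, was -1.29 to -0.39 with 1 library left out (adjusted p = 0.055 to 0.87, camera). With the replicate block, 2570 loci were higher and 2067 lower, and 3769 of the 4599 calls were shared; of the named loci, Potra002011g15769 lost its call (adjusted p = 0.057). No label says that equal numbers mark a shared batch. For this reason the main fit was planned without a block. The deviations of equal-numbered libraries from their group means correlated at 0.37, 0.18 and 0.04 across loci. Not every library correlated best with its own number: wild-type replicate 3 correlated at 0.39 with MYB117 replicate 2. These values do not decide whether equal numbers mark a shared batch. The odds ratio for unnamed loci was 3.07 to 8.08 over all alternatives, and of the refitted values of named loci and hairpins, 270 kept their side of the test, 27 lost their call and 1 gained one. Not counted there are Potra002011g15769 with DESeq2 and Potra002398g18252 with the minimum of 1 CPM, which had no adjusted p. The alternatives for the level of MYB117, the gene lists and the B-ring ratio were not run. Thinned to the smallest library, the counts gave 2578 higher and 1874 lower loci and 2 hairpin calls. Low counts kept all but 30 of the 425 hairpin loci out of the test.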

Other observations

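In this part, the 16-fold limit, the thinning, the matching on level, the test of loci alone on their prefix and the shuffling among prefixes of like size were chosen after the data were seen. Among hairpins outside the tests, ptc-MIR6424 had 68 and 44 reads in wild-type replicates 2 and 3, 0 in wild-type replicate 1, and 0, 2 and 0 in the MYB117 libraries. The locus ptc-MIR530b was at 26.2 CPM in wild-type replicate 1 and 7.12 CPM in MYB117 replicate 1, and between 0.324 and 2.44 CPM in the other 4 libraries, a pattern by replicate number and not by genotype (log2 fold change -1.91, SE 1.46, adjusted p = 0.40, edgeR). Wild-type replicate 1 also held 13.4% of its reads in its 10 most abundant loci, against 5.86% to 8.70% in the other libraries. Every wild-type library lay above every MYB117 library in this share, at 10.3% ± 2.73 and 6.82% ± 1.59 (n = 3 each, exact permutation p = 0.1, the smallest possible, and 0.16 after adjustment over 13 library measures), though the closest were 8.67% and 8.65%. Loci that were alone among tested loci on their identifier prefix rose more often than others: 559 of 3804 (14.7%) against 1659 of 20125 (8.24%; odds ratio 1.92, 95% interval 1.73 to 2.13, Fisher's exact p = 1.7e-32), while falls were at 6.70% and 7.81%. Loci of the same prefix that did not pass the filter were not counted.

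Large rises outnumbered large falls by 402 to 28 loci, and 3 technical explanations were tested. With all libraries thinned to the smallest total, the lowest ratio of rises to falls in 5 draws was 13.96, which argues against sequencing depth. The lowest ratio under RLE and upper-quartile scaling was 14.25, but these scalings moved the median log2 fold change of all loci, -0.06, only to -0.06 and -0.08, so library scaling stays open. Among loci with at least 10 CPM in the group where they were higher, 132 rose and 8 fell by 16-fold, a ratio of 16.5, which argues against noise near the floor. An effect of MYB117 and a difference between transformed and untransformed plants that is unrelated to MYB117 both remain open and untested, since no vector control was analysed here.

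Changed unnamed loci rose in 82.4% of cases. Identifier loci matched on mean level gave a median of 59.0% (central 95% of 10000 draws 54.4% to 63.7%), which argues against a low level as the cause. Among the 401 changed unnamed loci with no adjacent locus number changed in the same direction, 79.6% still rose (Fisher's exact p = 4.5e-23 against identifier loci), which argues against pieces of neighbouring genes as the whole cause; that adjacent numbers are neighbours is an assumption. How the loci were assembled, and from which libraries, was not tested, and no biological explanation was tested.

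A further hypothesis was that neighbouring genes change together, with loci that share the digits before the g of their identifier taken as neighbours. Pairs in which both fell numbered 602, against a median of 471 in 10000 shufflings (permutation p = 1e-04, the smallest they can give). Pairs in which both rose numbered 604, against a median of 694 (permutation p = 0.997). As rises were more frequent on prefixes with a single tested locus, calls were also shuffled among prefixes with like numbers of tested loci. The pairs then exceeded the shuffled median 1.12 times for rises (permutation p = 0.0052) and 1.14 times for falls (permutation p = 0.0015), so a small excess may be present in both directions.

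The count of changed loci was compared with other splits of the libraries. The real split gave 4599 changed loci and the highest of the 9 others gave 0, so that 1 of the 10 splits was as large. With 10 splits the share cannot fall below 0.1. Each of the 9 others also had libraries of both groups on each side, so the difference between the groups entered their spread. Their 0 calls are therefore no separate support for the 4599.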
